A study of Mus musculus with 6 samples.

How the data were processed

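RNA sequencing libraries from brain tissue of C57 mice were compared between 3 libraries of a group with high sexual motivation and 3 libraries of a group with low sexual motivation, as the labels name them. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected on oligo(dT) beads, fragmented and reverse transcribed, and the second strand was made with dUTP and removed before amplification, so that the libraries keep the strand of the RNA. Whether strand was used in counting is not given in the sources used here, so reads of genes that overlap on opposite strands may not be separated. The labels do not name the tissue in 1 way: the series title names the medial amygdala and the design text uses the abbreviation MeA, the extraction protocol uses the abbreviation PrL, and the tissue label says brain. How sexual motivation was scored, and whether each library came from a separate animal or from pooled animals, is not given in the sources used here. The p-values then measure only the spread between these libraries, which may in part be technical.

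Gene expression values were deposited as FPKM (fragments per unit of transcript length and of mapped fragments), by the name of the deposited table, with 1 column per library. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with the mouse build GRCm38, with no versions or settings. The deposited table holds 13170 genes, has 0 values at 0, and its lowest mean FPKM over the 6 libraries is 0.500. Genes that the table does not list, among them Cyp19a1, Avpr1a and Xist, were not analysed here. In 20 places a gene symbol had been turned into a calendar date, and those entries were tested under the text as given and not named. The authors' deposited table also has a log2 fold change, which equals log2 of the mean FPKM of the high group over the mean of the low group in all 13170 entries. The p-value that the authors deposited equals that of an equal-variance test of the untransformed FPKM in all 13170 entries, within a tolerance of 1e-06, and carries no adjustment for the number of genes. Both identities were found by recomputing the columns, since the labels do not state the authors' test.

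FPKM carry no read counts, so no count model was fitted. FPKM were transformed as log2(FPKM + 1), genes with a mean FPKM of at least 1 over the 6 libraries were kept, and the high and low groups were compared with limma 3.58.1 in R 4.3.3, with a trend of variance on mean expression, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Every adjusted p given is from limma unless another source is named. A log2 difference is high minus low on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. For genes below the filter, values come from the same model fitted to all 13170 genes, and are described as unfiltered. The 33 gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes, against all tested genes, and the p-values were adjusted over the 33 lists. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives. Beside each count over all genes, a count adjusted over the list alone is given, which carries no adjustment for the number of lists. Single comparisons of FPKM used exact 2-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1. Principal components were computed on the centred log2 values. Gene positions are from the GENCODE annotation of GRCm38, to which 13055 symbols matched. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

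The groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except for 3 alternatives added after seeing the data: a spline trend on transcript GC content and length removed from each library, with 5 degrees of freedom, over the 11924 tested genes (99.2%) with both properties; the choroid plexus score of each library as a covariate; and a fit with low libraries 1 and 3 left out. Genes are named by 4 parts of that rule: the 10 genes per direction with the largest change among those past the threshold with separate groups, filled up by the smallest p where fewer passed, without predicted or unnamed gene models; Nrg1, Nrg2, Nrg3, Erbb2, Erbb3 and Erbb4; Esr1, Cyp19a1, Oxtr and Avpr1a; and up to 4 members of each list with the smallest p. Some genes that this rule takes are not reported here. The alternatives chosen in this way were other pseudocounts, filters and scalings, the replicate number as a block, array weights, no variance trend, robust fitting, rank-based list tests and each library left out in turn.

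Absolute depth is unknown. Relative depth was estimated from 1428 genes with FPKM under 1.5 in every library, as the most common ratio between libraries, on the assumption that low values are multiples of what 1 fragment is worth. That ratio was shared by 28 to 37 of these genes, against 10 to 14 at the next most common ratio, and was the same to 3 significant digits with low library 2 as the reference. With high library 1 set to 1, it was 1.33 for high library 2, 1.08 for high library 3, 0.960 for low library 1, 1.25 for low library 2 and 0.954 for low library 3. The sum of FPKM per library lay between 247560 and 253867. The procedure was tested on simulated data with the means and spread of the 12026 tested genes, in 5 simulated sets. Planted log2 changes of 0.5 were called in 81.6% of genes, of 1 in 99.2%, and of 2 and 3 in 100%, with 6.12% of calls false. A list with a planted shift was called in 5 of 5 sets and an unchanged list in 0 of 5. Noise was drawn independently for each gene, and changes were planted among the more highly expressed genes only. The simulated sets therefore cannot show how often camera calls an unchanged list whose genes are correlated, nor the recovery of genes with low expression. Each set also held many planted changes, most of them larger than 0.5, and these ease the Benjamini-Hochberg cut for the rest. The share recovered at 0.5 is thus too high for data in which few genes change.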

Results

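Poly(A) RNA profiles of mouse brain tissue were compared between male mice of high and of low sexual motivation, with 3 libraries in each group. The title of the series names signalling of the growth factor NRG1 through its receptor ErbB4 in the medial amygdala, so the genes of that pathway were examined first, followed by all genes and by lists of cell type markers and pathways. Values are mean FPKM ± SD over the 3 libraries of a group unless stated otherwise. The relative depth of the libraries spanned 0.954 to 1.33, with the deepest library in the high group and the next deepest, 1.25, in the low group. Male-specific transcripts were present in all 6 libraries, with Eif2s3y at 8.73 to 12.3 FPKM. Pearson correlations of log2 values between libraries lay between 0.979 and 0.991. The first principal component held 38.5% of the variance and did not separate the groups. On it low libraries 3 and 1 scored 19.6 and 9.27, while low library 2 (−3.46) lay among the high libraries (−11.8 to −2.81). High library 2 stood apart on the second principal component, which held 25.5% of the variance (score −20.2, against 2.28 to 5.43 in the other 5). It also had the lowest share of FPKM from mitochondrial genes, 11.1%, where the other libraries had 13.6% to 16.4%.

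Nrg1, which encodes a ligand of the ErbB receptors, was expressed at a low level and was lower in every high library than in every low library. Its FPKM was 0.447, 0.483 and 0.469 in the high group and 0.783, 0.785 and 0.717 in the low group, or 0.466 ± 0.0182 against 0.762 ± 0.0387, a ratio of 0.612. Erbb4, the receptor kinase named in the title, stood at 3.12 ± 0.921 in the high group and 3.63 ± 0.234 in the low group, with overlapping values. Nrg2 (3.52 ± 0.485 against 3.99 ± 0.183) and Nrg3 (3.80 ± 0.543 against 3.90 ± 0.512), which encode further ligands, overlapped as well, as did the receptor genes Erbb2 (0.525 ± 0.0960 against 0.662 ± 0.145) and Erbb3 (1.79 ± 0.119 against 1.49 ± 0.213). Hbegf, which encodes a ligand of EGFR and ErbB4, was the listed gene with separate groups in the other direction, at 4.74 ± 0.225 against 4.03 ± 0.358.

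None of these differences passed the test. For Nrg1, which lay below the expression filter, the unfiltered log2 difference was −0.26 (SE 0.0873), with an adjusted p of 0.571 over all genes and 0.245 adjusted over the list alone. The exact permutation p of its group means was 0.1, the smallest that this design can give. The authors' deposited table gives Nrg1 a log2 fold change of −0.708 on untransformed FPKM and an unadjusted p of 0.00028. That p ranks 7 among 13170 genes, where 3.68 genes would be expected at or below it by chance, and its Benjamini-Hochberg value is 0.438. Erbb4 had a log2 difference of −0.19 (SE 0.162; adjusted p = 0.737). Its mean in the high group rested on high library 2, at 2.05 FPKM where the other high libraries had 3.67 and 3.63, and without that library the difference was 0.0079. Hbegf had a log2 difference of 0.19 (SE 0.0816; adjusted p = 0.589). Of the 12 tested genes of the NRG-ErbB list, 5 were higher and 7 were lower, 0 passed over all genes and 0 adjusted over the list alone by limma, and 1 had an unadjusted p under 0.05. The list as a set gave an adjusted p of 0.828. Nrg1 lies on chromosome 8 from 31814551 to 32884029 and Erbb4 on chromosome 1 from 68032186 to 69108059 in GRCm38.

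**Figure D1:**
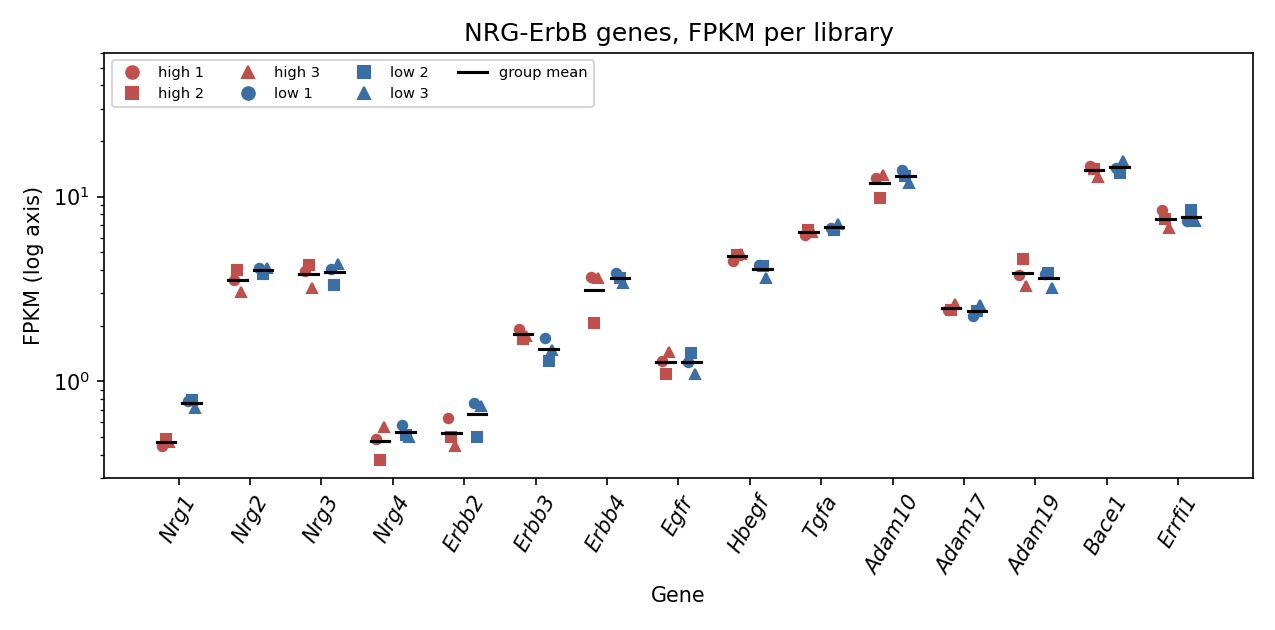
FPKM of the 15 listed NRG-ErbB genes in each of the 6 libraries, on a log axis, with high libraries in red, low libraries in blue and a black line at each group mean. Nrg1 lies between 0.447 and 0.483 in the high libraries and between 0.717 and 0.785 in the low libraries, and Erbb4 of high library 2 lies at 2.05.

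Among receptors for sex steroids and social peptides, Esr1, the gene of oestrogen receptor alpha, was lower in every high library, at 0.652 ± 0.185 against 1.06 ± 0.116 (unfiltered log2 difference −0.32, SE 0.113; adjusted p = 0.575). Greb1, an oestrogen-induced gene, stood at 0.449 ± 0.221 against 0.953 ± 0.122 (unfiltered log2 difference −0.44, SE 0.132; adjusted p = 0.560). The oxytocin receptor gene Oxtr (4.76 ± 0.839 against 5.29 ± 0.141) overlapped between the groups. The list of sex steroid receptors and enzymes had 4 of 11 tested genes higher and 7 lower, with 0 past the test over all genes, 0 adjusted over the list alone and an adjusted p of 0.563 for the list. In the list of social neuropeptides and receptors, Oxt, the oxytocin gene, had 2.83 ± 1.94 against 0.550 ± 0.367, and Crhr1, a receptor for corticotropin-releasing hormone, had 9.10 ± 1.2 against 7.32 ± 0.156. Grp, the gene of gastrin-releasing peptide, had 10.6 ± 2.01 against 15.4 ± 3.65. Of 19 tested genes in that list, 12 were higher and 7 were lower, 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 0.735 for the list).

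Over all genes, the largest contrast relative to its error was that of Stac2, an adaptor of calcium channels, at 32.6 ± 1.62 in the high group against 23.4 ± 0.565 in the low group (log2 difference 0.47, SE 0.0616). The next genes by p that were higher in the high group were Iglon5, a neuronal adhesion molecule (17.7 ± 0.304 against 13.1 ± 0.750), Pglyrp1 (3.68 ± 0.110 against 2.34 ± 0.144) and the collagen gene Col16a1 (11.7 ± 0.370 against 8.79 ± 0.224). Adamts2, Fsd1, Vamp1, Crabp1, H2-T22 and Rph3a completed the 10. The 10 genes that were lower included Ttc21a (0.368 ± 0.0153 against 1.92 ± 0.612), Dnali1, a light chain of axonemal dynein (0.433 ± 0.0472 against 1.71 ± 0.424), Rfx3, a transcription factor of ciliogenesis (3.08 ± 0.475 against 5.27 ± 0.347), Cfap206 (0.691 ± 0.121 against 2.14 ± 0.604) and Foxj1, a regulator of motile cilia (1.78 ± 0.247 against 5.51 ± 2.21). Of these, Foxj1 is a member of the list of ependymal cells and motile cilia. The others were Mef2c, a neuronal transcription factor (11.6 ± 1.32 against 17.4 ± 0.320), Trhr, the receptor for thyrotropin-releasing hormone (2.72 ± 0.701 against 6.07 ± 1.06), Kcnv1, Insl5 and Thbs4.

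These 20 genes were taken by the smallest p in each direction, and none passed. Of 12026 genes tested, limma called 0 at an adjusted p under 0.05 and 0 at 0.1, with a smallest adjusted p of 0.363. At an unadjusted p under 0.05 there were 1009 genes, 495 higher and 514 lower, where chance would give 601.3. Without the filter, 0 of 13170 genes passed and 1105 had an unadjusted p under 0.05. The groups did not overlap in 1796 genes, or 14.9%, where chance gives 10%. The authors' deposited table has 975 genes with an unadjusted p under 0.05, 499 higher and 476 lower, where chance would give 658.5. Of them, 24 differed at least 2-fold, 5 higher and 19 lower, and 0 passed after Benjamini-Hochberg adjustment. The median standard error of a log2 difference was 0.0900. Leaving out each library in turn called 0 genes each time.

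Genes of ependymal cells and motile cilia formed the list with the smallest p, and were lower in the high group. Of 11 tested members, 10 were lower and 9 had separate groups, with a median log2 difference of −0.68. Dynlrb2, a dynein light chain, had 0.685 ± 0.174 against 3.84 ± 2.24, and Ccdc153 had 1.38 ± 0.316 against 3.26 ± 0.999. Over all genes 0 members passed, and 9 passed adjusted over the list alone, Foxj1, Dynlrb2, Ccdc153, Tekt1 and Rarres2 with the smallest value, 0.0056. Cfap126 exceeded 0.05 without high library 1 (0.0576) or high library 3 (0.0701). Rsph1 stayed under 0.05 only without low library 2 (0.00477), and reached 0.0895 without high library 3. The list had an adjusted p of 7.59e-10 with the preset correlation, and an adjusted p of 0.666 with an estimated correlation. All 3 low libraries contributed, with median ratios to the mean of the high libraries of 2.05, 1.79 and 2.46.

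Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were lower in the high group too, but their difference came from low libraries 1 and 3. The median ratio to the mean of the high libraries was 7.77 in low library 1, 1.07 in low library 2 and 30.3 in low library 3. Ttr, which encodes transthyretin, had 1290, 73.5 and 4016 FPKM in the low libraries and 62.3, 102 and 33.5 in the high libraries. Kcne2 had 5.70, 0.507 and 22.1 in the low libraries and 0.225 ± 0.0697 in the high group. Of 18 tested members, 17 were lower, 0 passed over all genes and 0 adjusted over the list alone, with a median log2 difference of −1.52. The adjusted p was 4.99e-09 with the preset correlation, and 0.739 was the adjusted p with an estimated correlation. With low libraries 1 and 3 left out, which leaves 1 low library assumed to vary like the high libraries, the list was no longer lower and its adjusted p was 0.385. In that fit, which takes its spread from the high libraries alone, the list of ependymal cells and motile cilia had a median of −0.42 and an adjusted p of 9.38e-06. Leaving out low library 3 alone brought the choroid plexus median to −0.93, and leaving out low library 2 brought it to −2.33.

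**Figure D2:**
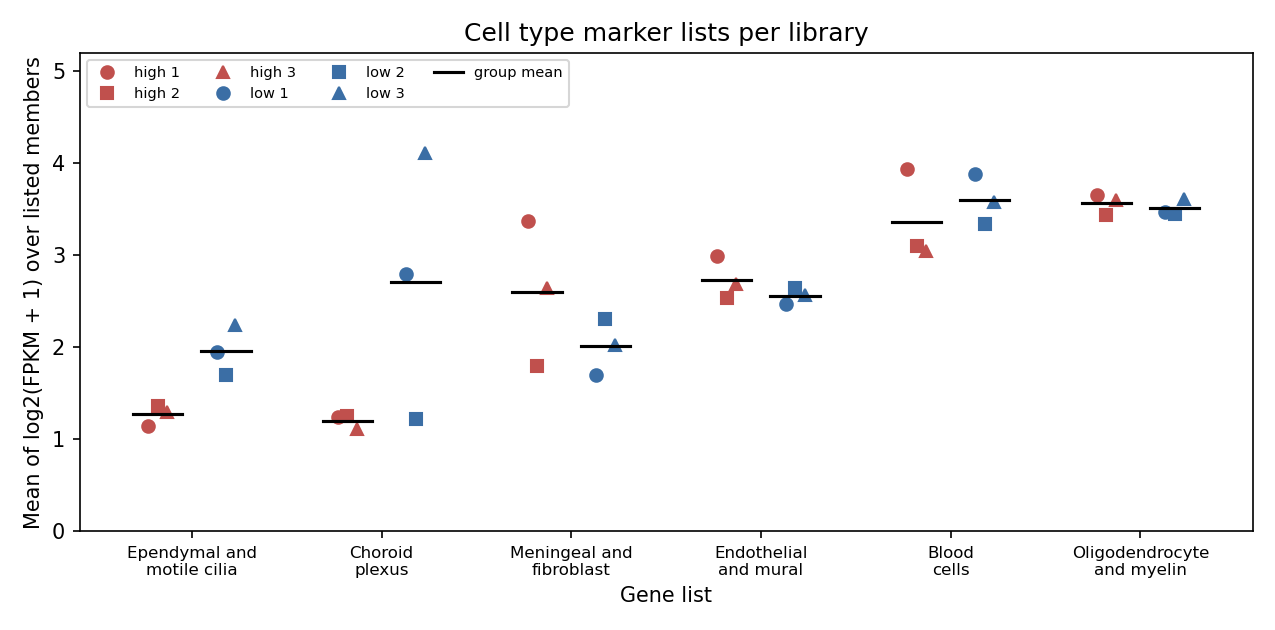
Mean log2(FPKM + 1) over the listed members of 6 marker lists in each library, with high libraries in red, low libraries in blue and a black line at each group mean. The choroid plexus score is 2.79 and 4.12 in low libraries 1 and 3 and 1.23 in low library 2, and the meningeal score is highest, 3.37, in high library 1.

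Most myelin genes were higher in the high group by a small amount. Of 21 tested members of the oligodendrocyte and myelin list, 19 were higher and 7 had separate groups, with a median log2 difference of 0.17. Mobp, a structural myelin protein, had 47.4 ± 1.61 against 38.4 ± 2.33, and Mog, a protein of the myelin surface, had 12.8 ± 0.842 against 10.1 ± 0.788. Hapln2, which encodes a link protein of the nodes of Ranvier, had 4.88 ± 0.758 against 3.37 ± 0.151. Over all genes 0 members passed, and 4 passed adjusted over the list alone, these 3 and Nkx6-2 (5.03 ± 0.675 against 3.23 ± 0.867). Each of the 4 exceeded 0.05 without high library 1, high library 3 or low library 1, to at most 0.158. The list had an adjusted p of 1.49e-05 with the preset correlation, and an adjusted p of 0.666 with an estimated correlation. The median was 0.10 without high library 1 and 0.11 without low library 1, and the list passed each time. Enpp2, which is shared with the choroid plexus list, had a log2 difference of −2.35. The mean log2(FPKM + 1) over listed members, which includes Enpp2, overlapped between the groups. It was 3.66, 3.44 and 3.61 in the high libraries and 3.47, 3.45 and 3.61 in the low libraries. Oligodendrocyte precursor markers did not pass, with 3 of 11 higher and 8 lower (adjusted p = 0.501).

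Markers of meninges and fibroblasts were higher in the high group with a wide spread between libraries. Of 14 tested members 11 were higher, with a median log2 difference of 0.67 and 0 members with separate groups. Slc6a13, a transporter of the leptomeninges, had 11.8, 2.43 and 5.86 FPKM in the high libraries and 0.829, 3.92 and 0.683 in the low libraries, and Spp1, which encodes osteopontin, had 14.3 ± 10.9 against 3.55 ± 1.68. The adjusted p was 0.00393 with the preset correlation and the adjusted p was 0.739 with an estimated correlation. Without high library 1 it was 0.244 with a median of 0.25, without low library 1 it was 0.0504, and without high library 2 the median was 1.05. With only genes at a mean FPKM of at least 5, the median was −0.01 and the adjusted p 0.625. Endothelial and mural markers, with Acta2 of smooth muscle at 14.8 ± 10.4 against 5.70 ± 2.26 and Cdh5 of endothelium at 4.83 ± 1.23 against 3.37 ± 0.372, were higher in 13 of 19 tested members, with a median log2 difference of 0.11. Their adjusted p was 0.0486 with the preset correlation, with an adjusted p of 0.739 with an estimated correlation. It exceeded 0.05 when high library 1, high library 3, low library 1 or low library 3 was left out, to at most 0.348, and the median was 0.03 without high library 1 and 0.21 without high library 2. In both lists 0 members passed over all genes and 0 adjusted over the list alone.

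Cytosolic ribosomal protein genes were higher in 44 of 51 tested members, by a median log2 difference of 0.09, and nuclear-encoded respiratory chain genes in 35 of 45, by a median of 0.06. Rpl41 had 254 ± 15.9 against 215 ± 13.3, while Rpl15 had a log2 difference of −0.34 (SE 0.109), and Cox5a, a subunit of cytochrome c oxidase, had 18.6 ± 1.03 against 16.0 ± 0.104. The adjusted p was 0.00059 for the ribosomal list and 0.00749 for the respiratory list with the preset correlation, and for both the adjusted p was 0.739 with an estimated correlation. In both lists 0 members passed over all genes and 0 adjusted over the list alone. The deviation of each library from the mean of the other libraries followed transcript GC content to different degrees. Its Spearman rho across genes, which are not independent replicates, was 0.437 in high library 2 and −0.490 in low library 2. Each rho is thus relative to the other libraries. The difference between the groups itself followed GC content (rho 0.387) and transcript length (rho −0.225) over 11924 genes. This trend therefore lies along the comparison of all genes, not only of these lists. After a trend on GC content and length was removed, the medians were 0.05 and 0.03 and the adjusted p-values 0.0882 and 0.0854, while the myelin list had a median of 0.16 and an adjusted p of 9.23e-06. Without low library 1 the ribosomal list had a median of 0.05 and an adjusted p of 0.0885, and the respiratory list a median of 0.0102 and an adjusted p of 0.401. The adjusted p of the ribosomal list was also 0.0544 without high library 3 and 0.0626 without low library 3, and its median was 0.05 without low library 3 or high library 2 and 0.13 without low library 2. Without high library 2 the respiratory list had a median of 0.03 and an adjusted p of 0.230.

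Hypothalamic peptides and factors were higher in 6 of 7 tested members, with a median log2 difference of 0.30 and an adjusted p of 0.00759 with the preset correlation, against an adjusted p of 0.666 with an estimated correlation. Their largest difference was that of Oxt, the 1 member that passed adjusted over the list alone (0.0394), with 0 past over all genes. Its FPKM was 1.57, 1.86 and 5.06 in the high libraries, and its value adjusted over the list alone was 0.0518 without high library 3, 0.0926 without low library 1 and 0.144 without low library 3. Avp, the vasopressin gene, had 15.8 FPKM in high library 3 and 1.02 to 3.41 in the other 5 libraries. The adjusted p of this list was 0.058 with a median of 0.23 after the GC and length trend was removed, 0.0544 with a median of 0.29 without high library 3, and 0.0626 with a median of 0.25 without low library 3.

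**Figure D3:**
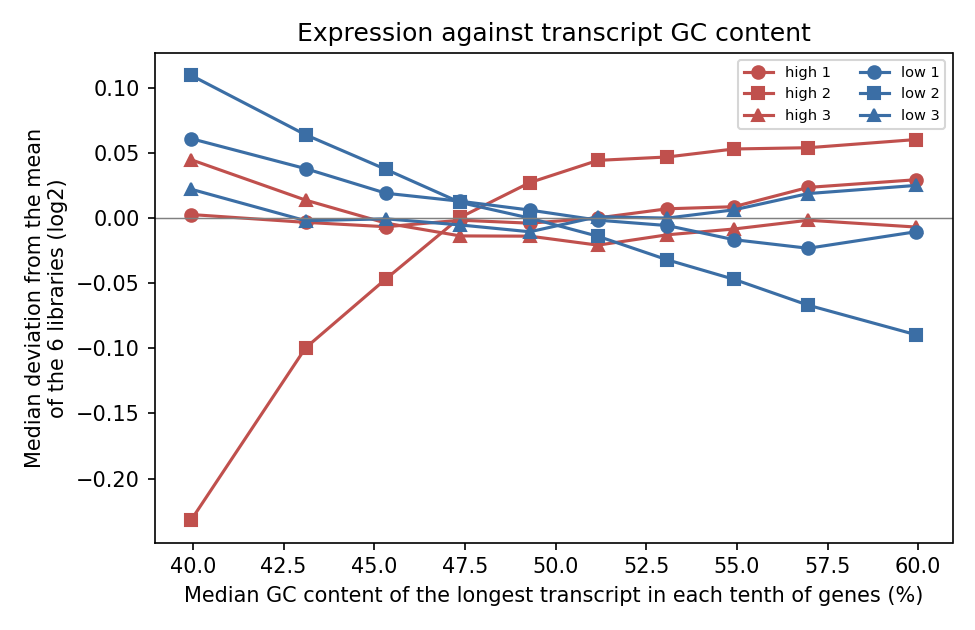
Median deviation of log2 expression from the mean of the 6 libraries, in 10 groups of genes ordered by the GC content of their longest transcript, for each library. High library 2 lies at −0.23 in the group of lowest GC content and 0.06 in that of highest, and low library 2 at 0.11 and −0.09.

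The other neuronal lists did not pass. GABA neurons and GABA receptors had 9 of 23 genes higher and 14 lower (adjusted p = 0.203), with the receptor subunit gene Gabra2 at 21.4 ± 2.14 against 27.0 ± 0.749. Glutamate neurons and receptors had 13 higher and 13 lower (adjusted p = 0.816), with Gria3 at 19.7 ± 0.944 against 23.7 ± 1.11 and Grin2d at 6.38 ± 0.424 against 4.97 ± 0.348. Cortical and hippocampal excitatory markers had 8 of 25 higher (adjusted p = 0.289), and Mef2c and Neurod1, at 1.55 ± 0.491 against 2.83 ± 0.145, passed adjusted over the list alone. Among interneuron markers, with 9 of 13 higher (adjusted p = 0.178), 3 calcium or nitric oxide signalling genes passed adjusted over the list alone, namely Calb1 for calbindin (29.2 ± 3.83 against 38.1 ± 1.25), Calb2 for calretinin (51.1 ± 9.06 against 36.1 ± 3.27) and Nos1 for neuronal nitric oxide synthase (29.6 ± 2.69 against 22.9 ± 2.44). Calb1 was also the 1 member to pass in this way among medial amygdala and subpallial factors, which had 9 of 15 higher (adjusted p = 0.997) and whose test pointed down while its median was 0.05. In the other neuropeptides and opioids, 14 of 22 were higher (adjusted p = 0.0863), with Adcyap1, the gene of the peptide PACAP, at 11.2 ± 1.52 against 7.83 ± 1.14 and Vgf at 112 ± 9.25 against 90.6 ± 6.85. Immediate early genes had 12 of 23 higher and a median of 0.00 with a test pointing down (adjusted p = 0.314), with Homer1 at 4.78 ± 0.529 against 6.23 ± 0.724. In the synaptic vesicle and release list, with 14 of 25 higher (adjusted p = 0.183), Vamp1, a vesicle fusion protein, had 11.5 ± 0.273 against 9.0 ± 0.440 and passed adjusted over the list alone. Voltage-gated ion channels had 15 higher and 15 lower, a median of −0.00 and a test pointing up (adjusted p = 0.508). The adjusted p was 0.856 for dopamine, serotonin and striatal genes, with 10 of 19 higher, 0.314 for thalamic and habenular markers, with 7 of 11 higher, and 0.340 for vomeronasal and olfactory genes, with 4 of 5 higher.

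Among glial and systemic lists, astrocyte markers were higher in 11 of 18 genes (adjusted p = 0.0666), with the connexin gene Gjb6 at 26.8 ± 2.41 against 19.7 ± 2.67. Microglia markers were higher in 11 of 20 (adjusted p = 0.314), and the 3 complement genes C1qa, C1qb and C1qc each had separate groups, with C1qb at 39.4 ± 0.825 against 34.8 ± 1.21. P2ry12, a receptor gene of resting microglia, had separate groups in the other direction, at 11.6 ± 2.38 against 14.7 ± 1.52, and of the members with separate groups 5 were higher and 1 was lower. In the glucocorticoid response list, with 10 of 17 higher (adjusted p = 0.229), Plin4, a lipid droplet protein (2.61 ± 0.102 against 1.60 ± 0.287), and Sult1a1, a sulfotransferase (11.6 ± 1.06 against 8.77 ± 0.637), passed adjusted over the list alone. Hapln2 passed in this way among perineuronal net and extracellular matrix genes, with 9 of 12 higher (adjusted p = 0.0863). The interferon response list had 7 of 10 higher (adjusted p = 0.229), with Ifit3 at 5.01 ± 0.975 against 3.15 ± 0.615. Blood cell markers had 2 of 7 higher (adjusted p = 0.0863), with the globin gene Hbb-bt at 9.27 ± 3.20 against 15.1 ± 2.55. The adjusted p was 0.314 for the circadian clock, with 5 of 16 higher, 0.229 for heat shock and protein folding, with 9 of 22 higher, and 0.397 for mitochondrially encoded genes, with 3 of 13 higher. In each of the 25 lists that did not pass, 0 members passed over all genes, and 0 passed adjusted over the list alone where none is named.

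In all, 8 of 33 lists passed camera with the preset correlation, 6 higher and 2 lower in the high group, and 0 passed with an estimated correlation or by fry. The count was 5 without low library 1, 5 without low library 3 and 13 without high library 2. Single genes passed adjusted over a list alone in 24 cases, with Calb1 and Hapln2 counted once for each of their lists. That adjustment does not allow for the 33 lists, and 0 of these genes passed over all genes. Of the 24 cases, 16 were lost when some library was left out. Those that were not were Mef2c, Foxj1, Dynlrb2, Ccdc153, Tekt1, Rarres2, Rsph4a and Pifo, the last not tested without low library 3. Such refits share their libraries with the main fit, so they are not independent tests.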

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

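The GC and length adjustment, the choroid plexus covariate and the fit with low libraries 1 and 3 left out were chosen after the results were seen, and the other alternatives were planned. limma called 0 genes under each alternative that adjusted for the number of genes, while 1009 genes had an unadjusted p under 0.05. Of these, 36 differed at least 2-fold on the log2(FPKM + 1) scale. At low FPKM that cut is stricter than the 2-fold change in FPKM that was counted in the authors' deposited table. The smallest adjusted p over the alternatives was 0.0766, without high replicate 2. The 0 calls within the NRG-ErbB list stood under all 23 alternatives. The exact permutation test among them could make no call, since its smallest possible p is 0.1. Apart from that test, Nrg1, Nrg4 and Erbb2 entered only the fits with the filter at 0.1, with no filter or rescaled to equal sums. For Nrg1 the other alternatives therefore say nothing here, and its range without the filter is given below. The replicate numbers did not pair the samples, since same-numbered libraries had correlations of deviations of −0.09, −0.21 and −0.16, and with the number as a block 0 genes passed and 743 had an unadjusted p under 0.05. DESeq2 was not run because FPKM carry no counts, and robust fitting was not run for the lists because camera has no such option. With every listed gene at a mean FPKM of at least 0.5, the filter at 0.1 and no filter keep the same genes. Rescaling to equal sums raised every listed gene past the filter of 1, so that fit also tested all 13170 genes. It also made the pseudocount smaller relative to the values. Absolute depth is unknown, so no counting interval was given. The 8 lists became 3 at a mean FPKM of at least 5, 3 with the choroid plexus covariate, where the loss of the choroid plexus list is fixed by using its own members as the covariate, 0 with an estimated correlation and 0 by fry, and 5 to 13 with each library left out. The cause of the changes below was not tested, except that the estimated correlation lies well above the preset 0.01 in the lists that passed (0.141 to 0.910) and that fewer genes or samples enter some fits. The values that follow are adjusted p-values, which for a list that passed end the call where they exceed 0.05.

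With an estimated correlation, the adjusted p was 0.6664 for the ependymal, myelin and hypothalamic lists and 0.7387 for the choroid plexus, ribosomal, meningeal, respiratory and endothelial lists. By fry it was 0.2798 for the ependymal list, 0.4411 for the myelin and hypothalamic lists and 0.7029 for the other 5. At a mean FPKM of at least 5 it was 0.2549 for the hypothalamic (median 0.18), 0.1018 for the endothelial (0.12), 0.6252 for the meningeal (−0.01, with a test pointing up) and 0.09694 for the choroid plexus list (−1.62), and too few ependymal members were left for a test. After the GC and length adjustment it was 0.05799 for the hypothalamic list, whose median went from 0.30 (SD of members 0.492) to 0.23 (0.480). It was 0.0854 for the respiratory and 0.0882 for the ribosomal list. Medians went from 0.09 (SD of members 0.0951) to 0.05 (0.0963) for ribosomal and from 0.06 (0.0759) to 0.03 (0.0699) for respiratory genes. The medians of these lists were thus smaller and the SD of members changed little, but what ended the calls was not tested. The myelin list had 9.23e-06. With the choroid plexus covariate it was 0.3691 for the hypothalamic, 0.2634 for the endothelial and 0.182 for the meningeal list, and the ribosomal list (0.5885) reversed, as did the choroid plexus list (0.9333), for which the covariate tests nothing. With low libraries 1 and 3 left out, which leaves 1 low library assumed to vary like the others, it was 0.332 for the hypothalamic, 0.5444 for the endothelial, 0.385 for the meningeal and 0.2263 for the respiratory list, and the ribosomal list (0.2263) reversed, as did the choroid plexus list (0.385), for whose values those libraries were left out. Quantile normalization gave 0.09759 for the respiratory and 0.1021 for the ribosomal list. The endothelial list had 0.05898 at a mean of at least 0.1 and with no filter, 0.05045 with median-of-ratios rescaling, 0.05166 with the replicate block, 0.06678 with no trend and 0.0679 by ranks.

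With each library left out in turn, the adjusted p ranged from 0.006637 to 0.06263 for the hypothalamic, 0.0005026 to 0.3477 for the endothelial, 1.108e-08 to 0.244 for the meningeal, 0.0001786 to 0.4013 for the respiratory and 3.11e-10 to 0.08852 for the ribosomal list, the lowest without low replicate 2 there. The ependymal, choroid plexus and myelin lists passed each time. Of the 25 lists that did not pass, 11 passed under no alternative and 14 under at least 1. Leaving out 1 library gave 0.02352 to 0.2521 for other neuropeptides, 0.04095 to 0.846 for immediate early genes, 0.04505 to 0.6885 for glucocorticoid response, 6.691e-05 to 0.5278 for blood cells, 0.0471 to 0.5874 for interferon response, 0.0171 to 0.8877 for heat shock, 0.01054 to 0.5487 for synaptic vesicle, 0.03607 to 0.5531 for GABA, 0.0471 to 0.9913 for dopamine and serotonin, 0.045 to 0.8516 for thalamic, 2.385e-05 to 0.8877 for astrocyte, 0.01847 to 0.9587 for microglia, 0.02056 to 0.7113 for mitochondrially encoded and 0.04505 to 0.204 for perineuronal net genes. Array weights gave 0.03758 for other neuropeptides and 0.0419 for interferon response, which also had 0.0356 with the filter at 0.1 or none and 0.03504 rescaled to equal sums. The replicate block gave 0.009908 and the GC and length adjustment 0.04707 for blood cells, and the block changed no call but these and the endothelial one. With low libraries 1 and 3 left out, immediate early genes had 0.03132, glucocorticoid response 0.03163, heat shock 0.01242 and synaptic vesicle genes 0.03207.

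Of 150 named genes followed through the alternatives, Nrg3 had a log2 difference of 0.1367 with the choroid plexus covariate, 0.1435 with low libraries 1 and 3 left out, and −0.1158 to 0.06424 with 1 library left out, against −0.03. Erbb2 was at 0.02673 with low libraries 1 and 3 left out, and Erbb4 at −0.2988 to 0.007881 with 1 library left out, the highest without high replicate 2. With the choroid plexus covariate Bst2 was at 0.1258 and mt-Co3 at 0.3439. With low libraries 1 and 3 left out Bst2 was at 0.05268, Cdhr1 at 0.01212, Hbb-bs at 0.01103 and mt-Co3 at 0.128, and array weights gave mt-Co3 0.04184. With 1 library left out, mt-Co3 ranged from −0.7964 to 0.05809, mt-Atp6 from −0.9195 to 0.3739, mt-Nd1 from −0.412 to 0.08933 and mt-Nd2 from −0.4205 to 0.07975, the last 3 highest without high replicate 2. No named gene passed under any alternative, with a lowest adjusted p of 0.0766, and the other 3046 values kept their sign.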

Other observations

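The choroid plexus and ventricle wall tests, the tests of Nrg1 against depth and choroid plexus and the count of splits for genes were chosen after the results were seen. The GC and length adjustment was also added after seeing the data, but its tests were fixed before the adjusted values were seen. The test of Nrg1 among all genes and the count of splits for lists were chosen before their results were seen. In the next paragraph, Otp and Th were taken by the rule for named genes and Ddx3y belongs to a sex check fixed before the data were examined, and the others were chosen after their values were seen.

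Several markers of brain regions overlapped between the groups, but not all did. Of the tested medial amygdala and subpallial factors, 1 was higher and 1 was lower with separate groups. Among cortical and hippocampal excitatory markers 1 was higher and 3 were lower in that way. Ecel1 and Lhx6, listed among medial amygdala and subpallial factors, stood at 16.7 ± 2.30 and 8.47 ± 0.938 FPKM in the high group and 18.2 ± 1.77 and 8.66 ± 0.611 in the low group. The cortical factors Tbr1 and Cux2 stood at 12.3 ± 2.49 and 6.80 ± 0.743 against 12.9 ± 1.68 and 7.50 ± 0.495. The vesicular glutamate transporter gene Slc17a7 had 191 ± 59.6 against 198 ± 30.2, and Gad1, which encodes an enzyme of GABA synthesis, 53.2 ± 7.85 against 53.9 ± 5.24. Otp, a factor of hypothalamic and amygdalar neurons, had 2.74 ± 0.886 against 1.40 ± 0.251 with separate groups (log2 difference 0.61, SE 0.172; adjusted p = 0.548), and Th, the tyrosine hydroxylase gene, had 1.05 ± 0.354 against 0.413 ± 0.0765 below the filter, also with separate groups. The Y-linked gene Ddx3y had 2.45 FPKM in high library 2 and 5.11 to 5.75 in the other 5 libraries, and the short mitochondrial gene mt-Atp8 had 3.35 in high library 2 and 13.9 to 102.6 in the others.

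Of the 20 listed choroid plexus markers, 19 were higher in low libraries 1 and 3 than in every high library, the exception being Slc5a5 (log2 difference 0.30), and in low library 2 their median log2 ratio to the high libraries was 0.092. A candidate explanation is choroid plexus tissue carried into those 2 dissections. It stays open, because it was drawn from these values, which therefore cannot test it. Ttr reached 4016 FPKM and Enpp2 409.6 in low library 3, against 102 and 22.9 as the highest values in the high group. In this list, Enpp2 is also a myelin marker and Prlr also a listed social peptide receptor. A biological difference in choroid plexus expression was not tested apart from this.

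For the ependymal and motile cilia genes, choroid plexus tissue as the whole source stays open. With the choroid plexus score of each library as a covariate, the median was −0.38 in place of −0.68. The list still passed camera (adjusted p = 1.58e-05, range over its alternatives up to 0.666). That pass cannot decide, since it rests on the preset correlation of 0.01, where the estimate for this list was 0.409. In low library 2 the median ratio to the high libraries was 1.79 for this list and 1.07 for choroid plexus markers, but that is 1 library. GC content and length are argued against as the whole cause, because the median was −0.719 after that trend was removed. A larger share of ventricle wall in the low libraries stays open: Rarres2, the 1 measured member without a role in cilia, was 1.73 times as high in the low group, and 1 gene cannot tell more wall from higher expression of cilia genes in the same cells. A biological difference between the motivation groups also stays open, and was not tested apart from the dissection.

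For Nrg1, the estimated relative depths of the groups overlapped, with low library 2 at 1.25 against 1 in high library 1, which argues against depth. With the choroid plexus score as a covariate the log2 difference was −0.293 (SE 0.123), against −0.26 without, which argues against that tissue as the source. The GC and length trend stays open, since its removal left −0.181 (SE 0.0921), or 68.3% of the difference, an interval that reaches below 50%. Chance among many genes stays open as well: 7 genes had a deposited p at or below that of Nrg1, 1.90 times the number chance gives. A biological difference between the motivation groups remains possible and, at this p, unproven; the adjusted p over the alternatives ranged from 0.279 to 0.987.

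The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split had 1009 genes at an unadjusted p under 0.05 and the highest of the others 942, so 1 of the 10 splits had a count as large. For the lists, 7 of the 10 splits had a count as large as the real 8, and the highest of the others was 14, for high libraries 1 and 3 with low library 2 against the rest, the same split that gave 942 genes. That split sets the libraries with few choroid plexus transcripts, other than high library 2, against the others.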
